A study of Bos taurus with 8 samples.

How the data were processed

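Peripheral blood leukocytes were taken from 8 Holstein heifers, 4 in the group IFNT6 and 4 in the group IFNT+PAG, and each heifer gave 1 library. Per the labels' protocols, RNA was extracted from 15000000 leukocytes with an RNA integrity number of 8 to 9.9, and paired reads of 100 bases were produced on a DNBSEQ instrument. The group of each library came from the treatment label, and the deposited column headers name the IFNT+PAG group PSPB6. The replicate numbers only name the heifers and pair none of them across groups, and the labels give no batch, pen or sequencing date. The design text also describes groups given the albumin vehicle or a shorter interferon course, which were not analysed here.

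The authors deposited 1 workbook with 2 sheets, and both sheets held identical counts for 16774 genes. Besides these, each sheet had 1 row among 16775 that named no gene, and that row was left out. The estimated counts (the "Read Count" columns per the file headers) were the authors' reads per gene and library, not normalized, and 93.7% of them were whole numbers. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.8 and DESeq2 without a version or a role for any of them. The genome build and annotation are not given in the sources used here. The deposited TPM values, scaled by the authors for gene length and to a fixed total per library, were read to compare the sheets. The deposited FPKM values, scaled by the authors for gene length and library size, gave the transcript length behind each gene. The authors' comparison of both groups was deposited as a log2 ratio with a p-value and a q-value per gene, and the test behind these columns is not given in the sources used here. Values from these columns are named as the authors' deposited table. Gene symbols and descriptions came from the files, and 450 genes without a symbol are given by their gene ID. The RefSeq table supplied with the data held 16037 of the gene IDs and gave no name that the files lacked. Genome positions were not used, because the build is not known.

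Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and test, TMM scaling, default filterByExpr with a minimum count of 10 and a minimum total of 15). This left 12759 genes. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and log2 fold changes are IFNT+PAG over IFNT6. The standard error of a log2 fold change was its size divided by the square root of the quasi-likelihood F statistic. CPM were computed from the counts after TMM scaling and are given as mean ± SD over 4 heifers. For a gene with 0 counts in all libraries of a group, a lower bound of the fold was taken against 3 counts in the smallest library of that group. Such bounds cover counting error only, since reads are not independent molecules.

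Gene lists of interferon responses, immune functions and blood cell markers were fixed before the data were examined. They comprised 31 lists with 846 symbols, of which 783 matched the files. The list of mitochondrially encoded genes matched 0 genes and was not tested, which left 30 lists with at least 5 tested members. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. A list score is the mean log2 CPM of the list's members in 1 heifer. Scores were compared by an exact two-sided permutation test over 70 assignments, which cannot give a p below 0.0286. KEGG, Reactome and GO biological process annotation in the deposited sheet was tested by camera over sets of 10 to 500 tested genes, with adjustment within each source.

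The named genes followed a rule fixed at the same time. It took up to 8 higher and 8 lower genes with a symbol, an adjusted p under 0.05, a mean of at least 1 CPM and group ranges that do not overlap, ranked by size of the log2 fold change. It added the 2 members of each list with the smallest p, and ISG15, MX1, MX2, OAS1X, RSAD2 and IFI6. Genes named outside the rule are marked as such.

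The 8 libraries held 20651482 to 22699634 estimated counts. On simulated counts for the same 12759 genes and library sizes with 200 changed genes, the edgeR test recovered 0 of 50 genes changed 1.5-fold, 23 of 50 changed 2-fold, 43 of 50 changed 4-fold and 46 of 50 changed 8-fold. It called 2 of the 12559 simulated genes that had no change. In a simulation of 30 lists of 25 genes with independent noise, camera called all 5 lists moved 1.5-fold and 0 of the others.

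Alternatives fixed in advance were DESeq2 1.42.0, RLE and library-size scaling, no filter or a filter of at least 1 CPM in at least 4 libraries, a robust fit, limma-voom with and without quality weights, removal of the 20 most abundant genes, and a covariate for the neutrophil minus αβ T cell score. A minimum log2 fold change of 1, a threshold of 0.10, the median or another prior count for list scores, and leaving out each heifer completed them. The removal or merging of gene copies, identified by their descriptions and not by sequence, and the estimated correlation without IFNT+PAG replicate 1, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with tables read through pandas 2.3.3 and numpy 2.4.6.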

Results

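Transcript levels were measured by RNA sequencing in blood leukocytes of 8 heifers given intrauterine infusions of proteins that the bovine conceptus secretes. Interferon tau (IFNT) is the signal by which the ruminant conceptus is recognised by its mother, and pregnancy-associated glycoproteins (PAG) are products of the trophoblast that enter the maternal blood. The 4 heifers of the group IFNT6 received 200 µg of IFNT per infusion of 20 mL on days 14 to 19 of the oestrous cycle. The 4 heifers of the group IFNT+PAG received the same IFNT over the same days, with 100 µg of PAG per infusion added on days 17 to 19. Infusions of both groups also held albumin at 200 µg per mL, and the heifers were 12 to 17 months old. Blood was drawn on day 20, 12 h after the last infusion. The comparison therefore addresses the difference with and without PAG in leukocytes of heifers that were all under IFNT, and no group without IFNT entered it. The labels give no batch, so a difference in processing between the groups cannot be told apart from an effect of PAG. Libraries held 21593545 ± 860706 estimated counts in IFNT6 and 21281507 ± 475666 in IFNT+PAG (SD, n = 4 each), a difference smaller than the spread between heifers (exact permutation p = 0.60). CD74, the invariant chain of MHC class II, was the most abundant transcript in each library. Pairs of libraries within a group differed by far more than counting noise, with a mean chi-square per gene of 38.3 to 216, so each heifer was counted once.

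Leukocytes of both groups differed in a small set of genes. Of 12759 tested genes, 38 passed an adjusted p of 0.05 in the edgeR test, 21 higher and 17 lower in IFNT+PAG, and the CPM ranges of both groups did not overlap for any of them. At an unadjusted p under 0.05 there were 2153 genes, where 638 would be met by chance. Ranges did not overlap for 1451 genes (11.4%, against 2.86% by chance for 4 against 4). Other splits of the same heifers into 4 and 4 gave up to 2180 genes at an unadjusted p under 0.05 and up to 1280 with ranges apart, so the first of these excesses was not particular to the treatment groups. On the first principal component, which held 32.9% of the variance, the difference between groups did not pass the test (exact permutation p = 0.0857, adjusted p = 0.229 over 4 components), and IFNT+PAG replicate 1 lay farthest out with a score of 65.6. DESeq2 called 636 genes on the same counts, and on simulated counts it called 36 of 12559 genes without a change, against 2 by edgeR. It also recovered 37 of 50 simulated genes changed 2-fold, against 23 by edgeR. The simulated counts were drawn with the dispersions that edgeR estimated, and the reason for the larger count was not tested. The edgeR count fell to 13 without IFNT6 replicate 1, 15 without replicate 2, 18 without replicate 3 and 22 without replicate 4 of that group, and to 21 without IFNT+PAG replicate 2 and 22 without replicate 3.

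Among the genes higher in IFNT+PAG than in IFNT6, CDKN2A, which encodes inhibitors of the cell cycle, went from 5.26 ± 1.25 to 18.7 ± 3.27 CPM (SD, n = 4 each; log2 fold change 1.83 ± 0.21 SE, adjusted p = 0.00837). LOC529792, described in the files as cytokine receptor like factor 2, rose from 12.4 ± 2.08 to 26.0 ± 3.56 CPM (adjusted p = 0.0368). KLF2, a transcription factor of resting lymphocytes, rose from 657.6 ± 30.0 to 1154 ± 84.5 CPM (log2 fold change 0.81 ± 0.10 SE, adjusted p = 0.0174). RPL28, a protein of the large ribosomal subunit, rose from 306.5 ± 16.3 to 577 ± 112 CPM (adjusted p = 0.0436). Among the genes lower in IFNT+PAG, ALOX12, a lipoxygenase of arachidonic acid found in platelets, went from 13.3 ± 5.68 to 1.53 ± 0.166 CPM (log2 fold change -3.12 ± 0.30 SE, adjusted p = 0.00363). RERGL, a RAS-like GTPase, fell from 6.60 ± 1.09 to 1.29 ± 0.348 CPM (log2 fold change -2.35 ± 0.26 SE, adjusted p = 0.00753). ALOX12 and RERGL kept their call without each of the 8 heifers in turn. The call ended for CDKN2A without IFNT6 replicate 1 (adjusted p = 0.0549). It ended for KLF2 without any 1 of 6 heifers and for RPL28 and LOC529792 without any 1 of 7, while their log2 fold changes stayed between 0.76 and 1.17 in all alternatives.

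**Figure D1:**
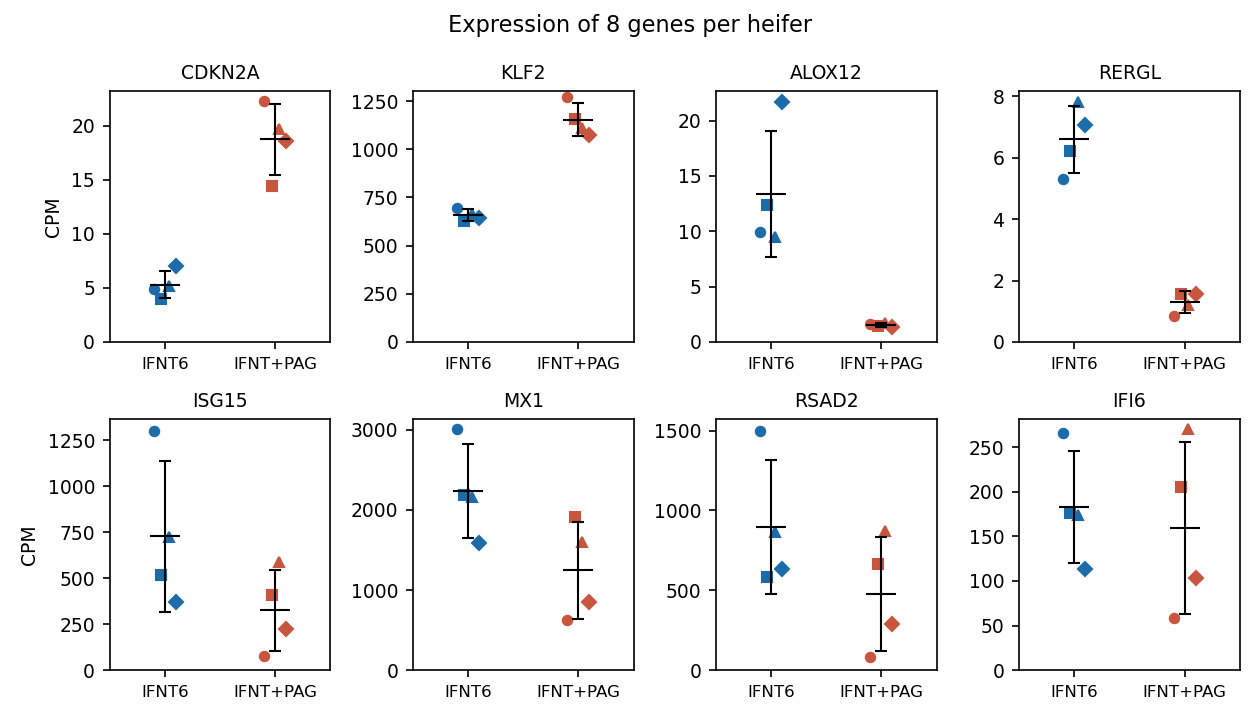
CPM after TMM scaling in each heifer (vertical axes, linear from 0) for 8 genes in both groups; symbols mark replicates 1 to 4, and the black bar and whiskers give the mean ± SD of 4 heifers. CDKN2A and KLF2 were higher and ALOX12 and RERGL lower in all 4 IFNT+PAG heifers, while the ranges of ISG15, MX1, RSAD2 and IFI6 overlapped.

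Most of the largest changes belonged to genes whose description matches or resembles that of another gene, called copies and parents here. How the reads of such pairs were assigned was not checked, so these values are uncertain. TMSB4, a copy of the actin-binding thymosin gene TMSB4X, fell from 106.4 ± 10.0 to 0.761 ± 0.175 CPM (139-fold lower, adjusted p = 1.79e-07), while TMSB4X stood at 1583 ± 126 and 1666 ± 290 CPM. LOC101906221 (ribosomal protein L36a-like) was 145-fold lower, LOC784052 (S26-like) 15.9-fold, LOC788801 (ferritin light chain) 11.3-fold and LOC101904084 (S14-like) 5.35-fold lower. In the other direction, LOC101904614, a copy of SMIM20, had 0 reads in all IFNT6 libraries and 27.4 ± 9.28 CPM in IFNT+PAG, at least 191-fold higher. LOC101903766, a copy of CHCHD5, had 0 reads in IFNT6 and 7.76 ± 1.70 CPM in IFNT+PAG, at least 53.9-fold higher. LOC101902561 (L21-like) was 16.6-fold, LOC617499 (SSU72) 4.73-fold, LOC107132247 (UBL5) 3.20-fold and LOC100337400 (STK17A) 1.90-fold higher. SMIM20 itself, named outside the rule, fell from 37.0 ± 2.85 to 17.3 ± 2.87 CPM (adjusted p = 0.0140). LOC101902760, described as ubiquitin and paired with no parent here, was 39.8-fold lower by the fit. Its IFNT+PAG libraries held 1, 3, 0 and 1 counts and those of LOC101906221 3, 2, 0 and 3, so both folds are imprecise. Their log2 fold changes ranged from -6.12 (without IFNT+PAG replicate 2) to -4.92 (without replicate 3) and from -7.45 (without replicate 4) to -6.77 (without replicate 3). Genes with a LOC symbol made up 16 of the 38 called genes and 655 of the 12759 tested ones (Fisher's exact p = 1.50e-11). LOC617499 lost its call without any 1 of the 8 heifers and LOC100337400 without any 1 of 7.

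**Figure D2:**
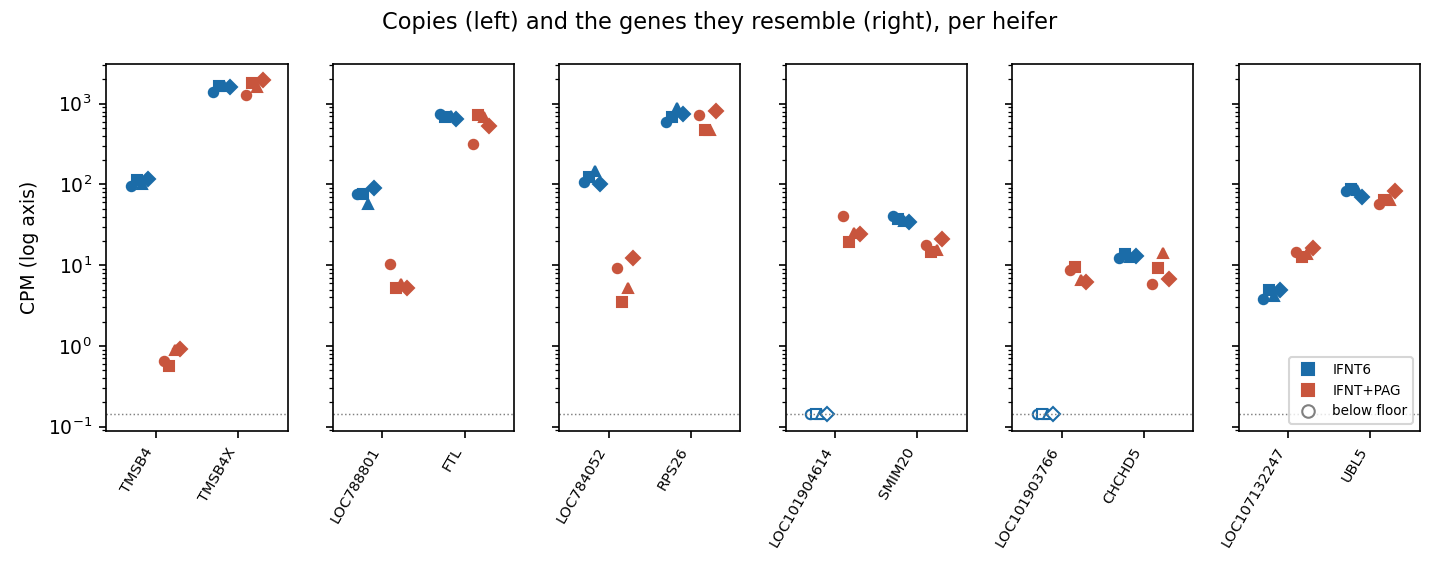
CPM after TMM scaling per heifer (vertical log axis) for 6 called copies (left in each panel) and the gene each resembles (right); symbols mark replicates 1 to 4, and open symbols are 0 counts drawn at the dotted floor of 3 counts. TMSB4, LOC788801 and LOC784052 were lower and LOC101904614, LOC101903766 and LOC107132247 higher in all 4 IFNT+PAG heifers, while the CPM of TMSB4X, FTL, RPS26, UBL5 and CHCHD5 overlapped between groups.

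Interferon-stimulated genes, the antiviral transcripts through which IFNT is read in blood, stood lower on average in heifers that also received PAG, with wide differences between animals. Of 57 measured members, 55 had a lower and 2 a higher estimate, and their median log2 fold change was -0.72. ISG15, a ubiquitin-like modifier, averaged 728 ± 410 CPM in IFNT6 and 325.1 ± 222 CPM in IFNT+PAG (log2 fold change -1.16 ± 0.59 SE, adjusted p = 0.345). MX1 averaged 2238 ± 586 and 1245 ± 606 CPM (adjusted p = 0.274), and RSAD2 896 ± 421 and 476 ± 358 CPM (adjusted p = 0.481). MX2 had a log2 fold change of -0.58 ± 0.50 SE, OAS1X of -0.15 ± 0.35 SE and IFI6 of -0.20 ± 0.45 SE. The smallest p within the list belonged to IFITM3 (log2 fold change -1.14 ± 0.31 SE) and UBE2L6 (-0.83 ± 0.25 SE). By edgeR 0 of the 57 members passed over all genes and 0 passed adjusted over the list alone. Camera called the list with the preset correlation (adjusted p = 1.79e-09), but not with an estimated correlation (adjusted p = 0.796), and fry did not call it (fry adjusted p = 0.471). The list score was 8.65 ± 0.34 in IFNT6 and 7.92 ± 0.80 in IFNT+PAG (SD, n = 4 each), with an exact permutation p of 0.20. IFNT+PAG replicate 1 had the lowest score, 6.88, and without that heifer the list's median was -0.37.

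The lists of interferon gamma responses and of interferon receptor signalling had medians in the same direction. Of 17 interferon gamma response genes 15 had a lower estimate (median log2 fold change -0.51, camera adjusted p = 0.0146; adjusted p = 0.796 with an estimated correlation). GBP5, a guanylate-binding protein, stood at -1.33 ± 0.45 and CIITA, the master regulator of MHC class II genes, at 0.58 ± 0.17 (log2 fold change ± SE). Of 21 receptor signalling genes 17 had a lower estimate (median -0.32, camera adjusted p = 0.0155; adjusted p = 0.796 with an estimated correlation), among them STAT2 at -0.83 ± 0.27 and JAK1 at -0.31 ± 0.11. Without IFNT+PAG replicate 1 camera called neither list, with adjusted p of 0.207 and 0.249, and single calls ended without IFNT+PAG replicate 4 (interferon gamma, adjusted p = 0.0535) and IFNT6 replicate 3 (receptor signalling, adjusted p = 0.0561). Sensors of viral and bacterial products followed, with 22 of 30 estimates lower (median -0.36, camera adjusted p = 0.0231; adjusted p = 0.796 with an estimated correlation), including MAVS at -0.39 ± 0.10 and TLR3 at -0.50 ± 0.15. That call ended without IFNT+PAG replicate 1 (adjusted p = 0.177), IFNT+PAG replicate 4 (0.0774) or IFNT6 replicate 3 (0.0651).

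Markers of T and NK cells were lower and markers of B cells higher in IFNT+PAG by the preset-correlation test. Of 27 αβ T cell markers 26 had a lower estimate (median log2 fold change -0.44, camera adjusted p = 4.97e-07; adjusted p = 0.796 with an estimated correlation), with CD27 at -0.55 ± 0.15 and CD6 at -0.57 ± 0.18. Of 22 NK and cytotoxic markers 20 had a lower estimate (median -0.60, camera adjusted p = 5.82e-05; adjusted p = 0.796 with an estimated correlation), with the lectin receptor KLRB1 at -1.45 ± 0.33 and granzyme A (GZMA) at -1.23 ± 0.40. KLRB1 was the 1 member that passed adjusted over the list alone (adjusted p = 0.0393). Of 23 B cell markers 20 had a higher estimate (median 0.41, camera adjusted p = 0.00142; adjusted p = 0.796 with an estimated correlation), with VPREB3 at 1.45 ± 0.34 and CD72 at 0.52 ± 0.14. The T cell score was 6.52 ± 0.08 and 6.08 ± 0.42, the NK score 3.74 ± 0.35 and 3.13 ± 0.37, and the B cell score 6.77 ± 0.23 and 7.15 ± 0.34 in IFNT6 and IFNT+PAG. Their exact permutation p were 0.0857, 0.0857 and 0.171. IFNT+PAG replicate 1 had the lowest T and NK scores and the highest B cell score, and without it the T cell median was -0.25 and the B cell median 0.24.

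**Figure D3:**
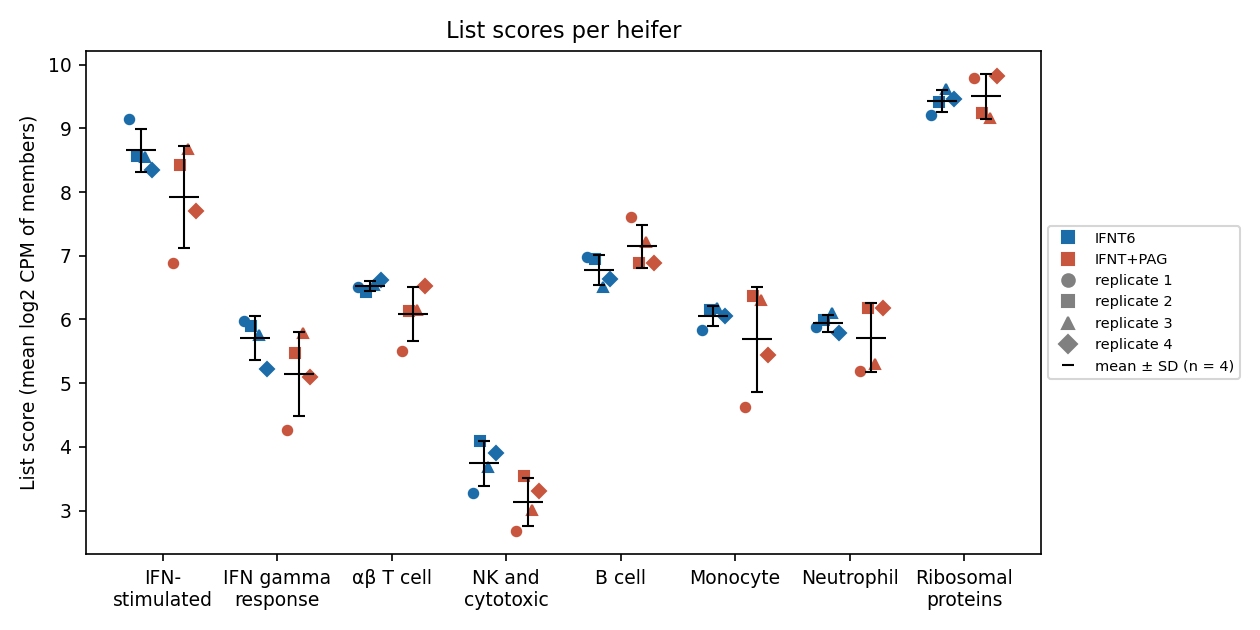
List scores, the mean log2 CPM of a list's members (vertical axis), per heifer for 8 lists in IFNT6 and IFNT+PAG; symbols mark replicates, and the black bar and whiskers give the mean ± SD of 4 heifers. Scores of both groups overlapped in each list shown, and IFNT+PAG replicate 1 lay lowest for the interferon, T cell, NK, monocyte and neutrophil lists.

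Other lists called with the preset correlation covered proliferation, checkpoints, migration, survival and monocytes. Cell cycle genes had 22 of 32 estimates lower (median log2 fold change -0.25, camera adjusted p = 0.00891; adjusted p = 0.799 with an estimated correlation), with CENPF at -0.65 ± 0.17 and the proliferation marker MKI67 at -0.64 ± 0.22. Of 25 regulatory and checkpoint genes 17 had a lower estimate (median -0.27, camera adjusted p = 0.0124; adjusted p = 0.796 with an estimated correlation), with the receptor TIGIT at -0.86 ± 0.22 and the ligand CD274 at -1.09 ± 0.43. This was the 1 list whose score separated all heifers of both groups, at 4.91 ± 0.04 in IFNT6 and 4.56 ± 0.39 in IFNT+PAG. Its exact permutation p of 0.0286 is the smallest the design allows (adjusted p = 0.514 over 30 lists). Adhesion and migration genes had a median of -0.22 (camera adjusted p = 0.0238, and adjusted p = 0.799 with an estimated correlation), with the chemokine receptor CCR5 at -1.05 ± 0.35 and the integrin ITGA4 at -0.78 ± 0.30. Monocyte markers had a median of -0.27 (camera adjusted p = 0.0468, and adjusted p = 0.804 with an estimated correlation), with CCR2 at -0.64 ± 0.27 and TLR8 at -0.43 ± 0.18. Apoptosis and survival genes had a median of -0.21 (camera adjusted p = 0.0468, and adjusted p = 0.796 with an estimated correlation). The survival factor BCL2 (0.83 ± 0.21) and the caspase inhibitor XIAP (-0.44 ± 0.12) were among the 3 members that passed adjusted over the list alone, 2 higher and 1 lower. Over all 30 lists camera called 12, 1 higher and 11 lower, while camera with an estimated correlation and fry's directional test called 0. List scores called 0 too (1 had an unadjusted p under 0.05). With a smallest p of 0.0286, no score could pass over 30 lists unless many reached it together, so that 0 says little. Without IFNT+PAG replicate 1 camera called 5 lists, and the checkpoint (adjusted p = 0.226), adhesion (0.612), monocyte (0.927) and apoptosis (0.252) lists were among those lost. Without IFNT+PAG replicate 1 the cell cycle adjusted p was 2.25e-10 and its score difference -0.38 (exact permutation p = 0.0286, adjusted p = 0.429), against -0.22 over all heifers. With an estimated correlation 0 lists passed by camera without that heifer either (adjusted p = 0.897 for the cell cycle list). The cell cycle call ended without IFNT+PAG replicate 2 (adjusted p = 0.0843) or 4 (0.122), the adhesion call also without IFNT6 replicate 3 (0.0636), the monocyte call without any 1 of 5 heifers and the apoptosis call without any 1 of 4.

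The remaining lists passed neither camera, fry's directional test nor the score test. Fry's mixed test, which asks whether members change in either direction, passed for the immediate early list (adjusted p = 0.0430) and for the apoptosis list (adjusted p = 0.0174). Of 76 cytosolic ribosomal protein genes 51 had a higher estimate (median 0.08, camera adjusted p = 0.207). RPL28 passed over all genes and RPL28 and RPS14 (0.73 ± 0.13) passed adjusted over the list alone. Of 30 immediate early and handling genes the median was 0.09 (camera adjusted p = 0.403), and KLF2 and IER2 (0.48 ± 0.10) passed adjusted over the list alone. IL1A, an inflammatory cytokine, passed in this way among 25 cytokine and chemokine genes (0.80 ± 0.18; list median -0.21, camera adjusted p = 0.224), where CCL5 stood at -0.79 ± 0.27. FECH, which inserts iron into haem, passed among 8 erythroid markers (0.65 ± 0.17; list median 0.28, camera adjusted p = 0.276), where KLF1 stood at 1.23 ± 0.43. Medians were -0.22 for neutrophil markers, with S100A8 at -0.95 ± 0.34 and LCN2 at 0.73 ± 0.27, and -0.41 for platelet markers, with NRGN at 0.75 ± 0.27 and ITGB3 at -0.63 ± 0.29 (camera adjusted p = 0.213 and 0.298). They were -0.32 for plasma cell markers (adjusted p = 0.160), with JCHAIN at -0.68 ± 0.24 and DERL3 at 0.56 ± 0.20, and -0.15 for γδ T cell markers (adjusted p = 0.318), with RORC at -0.74 ± 0.32 and GATA3 at -0.44 ± 0.22. For dendritic cell markers the median was -0.23 (adjusted p = 0.554), with IRF8 at -0.26 ± 0.10 and CCDC88A at -0.56 ± 0.23. Eosinophil and basophil markers had a median of -0.31 (adjusted p = 0.592), with IL3RA at -1.21 ± 0.87 and SIGLEC8 at 0.29 ± 0.29.

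MHC class I genes had a median of -0.16 (camera adjusted p = 0.0787), with CANX at -0.36 ± 0.12 and PSME1 at -0.38 ± 0.14. MHC class II genes had a median of 0.09, a mean of -0.19 and a camera direction upward (adjusted p = 0.409), with CIITA and BOLA-DOA (0.57 ± 0.17) first by p. T helper genes had a median of -0.39 (adjusted p = 0.185), with TBX21 at 0.69 ± 0.26 and CCR4 at -0.71 ± 0.30. Complement genes had a median of -0.13 (adjusted p = 0.409), with C1R at -0.86 ± 0.48 and ITGAM at 0.24 ± 0.14. Matrix remodelling genes had a median of -0.13 (adjusted p = 0.371), with SPP1 at -2.49 ± 0.88 and SERPINE1 at 0.38 ± 0.24. Glucocorticoid-responsive genes had a median of -0.13 (adjusted p = 0.472), with PER1 at 0.39 ± 0.13 and PIK3IP1 at 0.22 ± 0.10. Prostaglandin genes had a median of -0.17 (adjusted p = 0.785), with PTGDR at -0.59 ± 0.19 and PTGS1 at 0.67 ± 0.32. Progesterone and oestrogen receptor genes and targets had a median of 0.04, a mean of -0.04 and a camera direction downward (adjusted p = 0.855), with FKBP4 at 0.35 ± 0.16 and ESR1 at -0.77 ± 0.45. Camera called the MHC class I list without IFNT6 replicate 4 (adjusted p = 0.00532) or IFNT+PAG replicate 3 (0.0347), and the neutrophil list without IFNT+PAG replicate 2 (0.0187). With an estimated correlation over all heifers the adjusted p of these lists was 0.799 and 0.804. Camera with the preset correlation called the ribosomal list without IFNT6 replicate 3 (adjusted p = 0.0201), IFNT+PAG replicate 2 (0.0034) or 3 (0.000704), the cytokine list without IFNT+PAG replicate 2 (0.0134) and the platelet list without IFNT+PAG replicate 4 (0.0138). For these lists the adjusted p with an estimated correlation over all heifers was 0.855, 0.804 and 0.833. Among the 8 lists from MHC class I to the progesterone and oestrogen list, none of the members passed by edgeR, over all genes or adjusted over the list alone.

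Some of the annotated pathways called by camera covered interferon and cytotoxic functions. They rest on the same heifers and counts as the lists, so they are no separate support. Of the 35 splits of the heifers, 31 gave at least the 11 pathways called here. Camera with the preset correlation called 2 of 245 KEGG pathways, 7 of 427 Reactome pathways and 2 of 1020 GO processes. With an estimated correlation none of these sets passed in any source (adjusted p of at least 0.995). The Reactome sets for interferon signalling (27 genes, median log2 fold change -0.42, adjusted p = 0.0110), antiviral mechanisms of interferon-stimulated genes (17 genes, -0.54, adjusted p = 0.00207) and chemokine receptor binding (22 genes, -0.49 on average, adjusted p = 0.0137) were lower. The KEGG pathways of NK cell cytotoxicity (109 genes, median -0.24, adjusted p = 0.0434) and NOD-like receptor signalling (135 genes, median -0.15, adjusted p = 0.0244) were lower too. Mitochondrial translation (67 genes, median 0.13, adjusted p = 0.0253) was higher by the preset-correlation test. The GO processes of calcium-mediated signalling (41 genes, median -0.43, adjusted p = 0.0253) and SRP-dependent protein targeting to the membrane (15 genes, median -0.21, adjusted p = 0.0423) were lower by the same test.

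The authors' deposited table listed 567 genes with a q-value under 0.05, 397 higher and 170 lower in the group with PAG, and these included all 38 genes called here by edgeR. Its log2 ratios and the log2 fold changes computed here ranked the genes nearly alike (Spearman correlation 0.99996 across the 12759 tested genes, which are not independent replicates). Of the 567 genes, 552 were tested here and 15 were not. The authors' test is not given, so the cause of their larger count was not tested.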

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

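In 11 of 224 sets of 4 heifers, 1 heifer stood apart from the other 3 by Dixon's ratio of its gap to the range of the group (above the 95% critical value for groups of 4), and chance alone would give about 11. IFNT6 replicate 1 stood apart most often. Its score for eosinophil and basophil markers was 1.52, while the others lay between 3.18 and 3.28 (ratio 0.944). Its IL3RA was 22.0 CPM against 1.44 to 2.76 CPM (ratio 0.936), its JCHAIN 683 CPM against 434 to 450.2 CPM (ratio 0.935), and its TLR3 21.8 CPM against 28.7 to 28.8 CPM (ratio 0.975). IFNT+PAG replicate 1 was highest for BCL2 at 9.85 CPM against 6.99 to 7.03 CPM (ratio 0.989), for RPL28 at 744 CPM against 500.5 to 537 CPM (ratio 0.851) and for LOC788801 at 10.3 CPM against 5.17 to 5.84 CPM (ratio 0.871). IFNT+PAG replicate 3 had 5.70 CPM of IL3RA against 1.82 to 2.43 CPM (ratio 0.842), and IFNT+PAG replicate 4 had 24.0 CPM of TLR3 against 16.8 to 17.9 CPM (ratio 0.854). IFNT6 replicate 3 had 24.3 CPM of CD72 against 30.1 to 30.5 CPM (ratio 0.921), and IFNT6 replicate 2 had 0.368 CPM of LOC617499 against 0.760 to 0.816 CPM (ratio 0.875).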

How the results depend on the processing

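The removal and the merging of copies, and the estimated correlation without IFNT+PAG replicate 1, were chosen after seeing the data. The count of 38 genes became 636 with DESeq2 (442 higher, all 38 included), 80 with limma-voom and quality weights, 155 at a threshold of 0.10, 23 with an absolute log2 fold change of at least 1 and 14 with the cell mix covariate. It stayed between 30 and 43 with RLE or library-size scaling, no filter, the CPM filter, the robust fit, limma-voom and removal of the 20 most abundant genes. Without single heifers it ranged from 13 (without IFNT6 replicate 1) to 37 (without IFNT+PAG replicate 4). It fell to 7 when copies and their parents were left out and to 8 when copies were added to their parents. In the first of these, the log2 fold changes of the 21 called genes that were left moved by at most 0.0066 and their adjusted p rose to at most 0.0817, since fewer small p-values entered the adjustment. The 12 lists became 0 with an estimated correlation, 0 with fry and 0 with an estimated correlation without IFNT+PAG replicate 1. They numbered 5 (without IFNT+PAG replicate 1) to 14 without single heifers, and 10 to 13 under the other settings. List scores gave 0 lists in each setting run, but no score could pass unless many lists reached the smallest possible p together. The 11 pathways became 0 with an estimated correlation. The cause of these changes was otherwise not tested. No paired analysis was possible because the replicate numbers only follow the order of the samples and pair no heifers.

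Of the 18 called named genes, 12 kept their call without each heifer. The direction of 4 uncalled genes reversed. IL3RA ranged from -1.71 to 0.56 without single heifers (0.56 without IFNT6 replicate 1), SIGLEC8 from -0.066 to 0.45 (and -0.037 with the cell mix covariate), OAS1X from -0.45 to 0.049 and IFI6 from -0.58 to 0.083. Of the uncalled lists, 9 reversed without some heifer. Their adjusted p without single heifers ranged from 0.116 to 0.920 for complement, 0.000704 to 0.920 for ribosomal proteins, 0.0909 to 0.927 for eosinophil and basophil markers, 0.0669 to 0.841 for glucocorticoid-responsive genes, 0.0667 to 0.806 for immediate early genes, 0.0134 to 0.927 for cytokines, 0.0138 to 0.997 for platelets, 0.652 to 0.997 for progesterone and oestrogen targets and 0.358 to 0.927 for prostaglandin genes. The immediate early list also reversed with the cell mix covariate (adjusted p = 0.990), and complement, ribosomal proteins, eosinophil and basophil markers, glucocorticoid-responsive genes, cytokines and prostaglandin genes reversed with an estimated correlation without IFNT+PAG replicate 1 (adjusted p = 0.999 each). At this depth and number of heifers a 1.5-fold change was recovered for 0 of 50 simulated genes by edgeR, 1 by limma-voom and 6 by DESeq2, so most changes of that size would be missed by each of these tests.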

Other observations

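Of the tests below, both comparisons of copies with their parents were chosen only after the result was seen, as were the lists of other tissues.

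Heifers given the same infusions differed widely in their interferon transcripts. RSAD2 ranged from 80.9 to 871 CPM and ISG15 from 77.9 to 588 CPM within IFNT+PAG, and from 585.8 to 1500.4 CPM and from 368.7 to 1303 CPM within IFNT6. IFNT+PAG replicate 1, lowest for both, also had the lowest scores for monocyte markers (4.63, against 5.44 to 6.37 in that group) and inflammatory cytokines (2.70, against 3.62 to 4.24), and the highest cell cycle score (4.94, against 4.18 to 4.44).

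The 8 heifers can be split into 4 and 4 in 35 ways. For single genes chance was argued against but not excluded. Of the 35 splits 1, the real one, gave as many as 38 genes, the smallest share the design allows, and the highest other split gave 1. The splits were not repeated without the copies, where 7 genes were called. For gene lists chance could not be excluded, since 18 splits gave at least the 12 lists of the real one and the highest other gave 20. For annotated pathways 31 splits gave at least the 11 pathways of the real one and the highest other gave 281. Such splits point to a structure of the samples, or to a preset correlation below that of the genes, since 0 pathways and 0 lists passed by camera with an estimated correlation. Both can hold at once. For the interferon-stimulated list camera's p rose from 5.96e-11 to 0.263 with an estimated correlation, so the preset of 0.01 was too low there. What gave rise to the correlation was not tested. At an unadjusted p under 0.05, 2 splits gave at least the 2153 genes of the real one (highest other 2180), and 1 split gave as many as 1451 genes with ranges apart (highest other 1280).

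Copies, identified by their descriptions and not by sequence, made up many of the called genes. Variants carried by single animals were argued against as the whole cause, because 1 of 35 splits, the real one, gave 11 genes with at least a 4-fold gap and the highest other gave 2. Reads assigned to the copy in one group and to its parent in the other may explain the SMIM20 pair, where the copy was 27.4 CPM higher, SMIM20 19.7 CPM lower and the log2 change of their sum 0.27 (exact permutation p = 0.171). In 4 of the 14 pairs the summed CPM changed beyond its spread, which a move of reads alone would not give (LOC101906472 with TPM3 by -90.9 ± 14.2 SE, LOC782688 with SET by -58.4 ± 10.6, LOC107131728 with TMA7 by -28.5 ± 4.89 and LOC101904084 with RPS14 by 235.03 ± 50.9). The exact permutation p was 0.0286 each, the smallest possible (adjusted p = 0.0667). Group ranges of the sum were apart in 6 pairs, where 0.4 would be met by chance. LOC788801 with FTL (-201 ± 92.5 SE) and LOC100337400 with STK17A (43.8 ± 19.1) were also apart, but within the bound of spread. A parent can also change by itself, so a changed sum does not show what moved the copy. RPS14 rose by 245.5 CPM while its copy fell by 10.5 CPM, and SET and TMA7 fell by more than their copies. For TPM3 the copy fell by 104.9 CPM and TPM3 rose by 14.1 CPM, which argues against moved reads as the whole cause of that copy's fall. For STK17A the copy rose by 35.6 CPM and the parent by 8.11 ± 13.2 SE, where moved reads would lower the parent. Their sum stayed within the bound of its spread, so that pair is left open. In the remaining pairs a move of reads cannot be told apart from a change of the copies. Most parents were too abundant or too variable to show it, and 1 pair met both conditions set for it. A difference in processing between the groups, which the labels do not record, and the treatment itself stay open.

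Transcripts of uterus and skeletal muscle were split by group. Counted were genes with reads in at least 3 libraries of 1 group and none in the other. Over all 16774 genes these were 35 for IFNT+PAG and 65 for IFNT6. They numbered 1 of 10 liver genes, 1 of 5 kidney genes, and 0 of 13 brain, 12 luteal or ovarian, 7 mammary, 3 placental, 7 adipose and 5 lung genes. Of 32 uterine genes 5 had reads in all IFNT+PAG libraries and in none of IFNT6 (GRP with 20, 51, 25 and 101 reads, SERPINA14 with 9, 33, 8 and 24, and PENK, HOXA11 and KRT18). Of 22 skeletal muscle genes 7 had reads in at least 3 IFNT6 libraries and none in IFNT+PAG (ACTA1 with 65, 70, 130 and 1 reads). The lists were written after 8 of these genes had been seen, so their counts are no test of the split, and the members not seen before were KRT18, MYL1, TNNC1 and LDB3, with at most 7 reads in a library. Ratios between these genes did not differ detectably among 3 IFNT6 libraries for muscle (Monte Carlo chi-square p = 0.949, 397 reads). The same held among the 4 IFNT+PAG libraries for uterus (Monte Carlo chi-square p = 0.0688, 334 reads). One source per tissue would give this, but separate sources of the same tissue could too, so the test cannot show a single source. RNA from such tissues carried over at collection or library preparation is a candidate source, and transcription in the leukocytes was not tested.

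The lower interferon-stimulated genes may rest on another neutrophil to T cell mix or on 1 heifer, and neither can be told apart from an effect of PAG. With the cell mix covariate the list's median was -0.67, against -0.72 without it (score difference -0.65 ± 0.51 SE). The estimate thus changed little and stayed beyond -0.36, the bound of the rule fixed beforehand. The covariate subtracts the αβ T cell from the neutrophil score, and IFNT+PAG replicate 1 was lowest in both (5.51 and 5.19). A joint fall of both scores largely cancels in it, and it holds no monocyte or B cell score. This fit therefore says little about other changes of the cell mix. Without IFNT+PAG replicate 1 the median was -0.37, just beyond that bound (score difference -0.38 ± 0.32 SE). Both errors were too wide to separate the full difference from none.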
